A study of Mus musculus with 8 samples.

How the data were processed

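RNA sequencing was compared across 8 libraries of sorted mouse lung ILC3s, 2 for each of tissue and vascular cells at steady state and at 72 hours after infection with Pseudomonas aeruginosa. Per the labels' protocols, RNA was isolated with a miRNeasy Micro kit and libraries were made with the NEBNext Single Cell/Low Input kit, an amplifying protocol that does not mark strand, so reads of a gene and of an antisense partner cannot be separated. Per the submitters' processing notes, the tools were Trim Galore 0.6.6, HISAT2 2.2.1, SAMtools 1.2, featureCounts 2.0.3 and DESeq2 1.38.3 with the mm10 build, without their order or settings. The gene annotation, the treatment of reads shared by several genes and any filter were not given in the sources used here. Overlapping genes, paralogs and gene families such as the Klr, Ifit, Gbp and Mcpt genes are uncertain for that reason.

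The deposited values are a signal that is never negative: gene read counts divided by 1 size factor per library, as tested on the files. Within a library 100% of the values were whole multiples of 1 step, within a tolerance of 0.01 reads, and the implied factor equalled the median ratio size factor of the recovered reads in 8 of 8 libraries. The files listed 13880 genes, all with at least 41 reads over the 8 libraries, which is a mean of 5.125. No mitochondrially encoded gene was listed, so a mitochondrial share could not be computed. The recovered depth, 7015746 to 10343250 reads over the listed genes, limits the precision of low genes. Folds against a group without reads are lower bounds against 3 reads per library, and ratios with 1 to 3 reads in the lower group are given with an exact 95% binomial interval. These floors and intervals cover counting error only, since amplified reads are not independent molecules.

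Groups followed the labels. The libraries are numbered from 1 to 8 across groups, so no pairing is given. No replicate pair agreed within sampling noise: the chi-square of recovered reads per degree of freedom was 3.65, 7.14, 6.07 and 40.3 in tissue and vascular cells at steady state and in tissue and vascular cells after infection.

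The design fixed before the data were examined assumed read counts and edgeR's quasi-likelihood test. The files hold normalized values, and the reported test became limma 3.58.1 in R 4.3.3 on log2(value + 1). It used a 4-group means model over all 8 libraries, trended and robust empirical Bayes moderation and 4 residual degrees of freedom. Reads could be recovered, so the planned edgeR test, with TMM factors, could be run as well. At steady state it called 397 genes higher and 388 lower, against 1268 and 1318 in the reported fit. For infection in tissue cells it called 339 and 187, against 1755 and 1894. It called more for infection in vascular cells, 2303 and 3120 against 1257 and 2222. Genes with a value of at least 10 in at least 2 libraries were kept, 13560 in number, and an adjusted p below 0.05 by Benjamini-Hochberg was required. A weight per group was used, estimated from the data as 2.40, 0.992, 1.89 and 0.222 for tissue and vascular cells at steady state and tissue and vascular cells after infection. That choice was made after the files and the calls without weights had been seen, on simulated data with the dispersion of each group (0.00913, 0.046, 0.0163 and 0.501) and 200 genes changed.

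In those simulations, for the steady-state comparison, weighted limma found 50% of 2-fold and 91% of 4-fold changes among 13179 genes with 4 false calls, and unweighted limma found 0% of both. For infection in tissue cells it found 71% and 97% among 13149 genes with 8 false calls. For infection in vascular cells it found 1% and 11% among 13142 genes, and 23 of its 35 calls were false. For vascular against tissue cells after infection it found 0% and 1% among 13176 genes, with 2 of 3 calls false, and for the interaction 0% and 2% among 13156 genes, with 6 of 8 calls false. In these simulations the comparisons that use the infected vascular libraries had little power for changes up to 4-fold. For infection in vascular cells the share of false calls lay above the nominal level. The calls of the other 2 comparisons are too few to give a share. Without weights 24% of the 4-fold changes were found for infection in vascular cells and 14% between compartments after infection, with 70.7% of the calls false in both, and no call was made for infection in tissue cells or the interaction. In voom with quality weights 7 of 21 calls were false for infection in vascular cells, where it found 13% of the 4-fold changes, and 1 of 3 for the interaction, and it made no call between compartments after infection. The edgeR test with TMM factors made no call at steady state, for infection in tissue cells or for the interaction, and 64.7% and 63.2% of its calls were false for infection in vascular cells and between compartments after infection.

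Lists of genes, 28 in number with 639 entries of which 587 were listed in the files, were written before the data were examined. Some genes belong to several lists, so the list tests are not independent of each other. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, 2-sided, adjusted over the lists within a comparison. Genes named in the text are, per comparison, the 10 largest rises and the 10 largest falls (5 and 5 for the interaction) among genes past the threshold whose groups do not overlap and whose higher group has a mean of at least 10 CPM, leaving out predicted or unnamed genes. To these were added 16 genes followed in every comparison (Il7r, Il23r, Il22, Il17a, Il17f, Csf2, Ncr1, Ccr6, Tbx21, Gata3, S1pr1, Klf2, Cd69, Itgae and 2 more), and up to 4 members of each list with the smallest p in the direction described. Xist, the Y-linked genes, Cd3g and Cd3e in the account of the libraries were named outside this rule, Cd3g and Cd3e after their values had been seen. Some genes that the rule selects, among them the 2 followed genes left without a name, are not reported here, but they stay in every count of genes and of list members.

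Alternatives planned before the data were examined were DESeq2 1.42.0, edgeR 4.0.16 with median ratio factors, no filter, a filter on 10 CPM, voom with sample quality weights, fits on only the 2 groups compared, and leaving out each library. Added after seeing the data were limma without weights, pseudocounts of 0.5 and 8, TMM scaling and leaving out both infected vascular libraries. Added then too were a block on the number that ends the column name in each file, and the GC and length correction. The edgeR test with TMM factors, run on the recovered reads, was the test of the fixed design. The correction subtracted from each library's log2 deviation a robust local regression on GC content and log2 length over 12672 tested genes. GC content is that of a gene's longest transcript. Length is that of all its exons merged, and is called transcript length in the results. It replaced a form with an ordinary local regression after the results of that form, which shifted the bulk of the genes, had been seen. It also removes any biological change that follows these properties. Gene coordinates, GC content and lengths came from the GENCODE M21 annotation of the mm10 assembly, in which 12927 symbols matched 1 gene, 26 more than 1 and 927 none.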

Results

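RNA was sequenced from group 3 innate lymphoid cells (ILC3s), lymphocytes of barrier tissues that produce the cytokine genes Il22 and Il17a, sorted from the lungs of mice carrying an eGFP reporter. Cells of the lung tissue (tissue cells, tILC3) and cells of the lung vasculature (vascular cells, vILC3) were taken from untreated mice and from mice infected for 72 hours with the bacterium Pseudomonas aeruginosa. Each of the 4 groups held 2 libraries, and all 8 were used. Values are deposited normalized counts, given as mean ± SD of the 2 libraries of a group (n = 2). Changes are on the log2(normalized count + 1) scale, which understates the change of low genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another tool is named. Whether replicate libraries came from separate mice is not stated, so p-values measure only the spread between these libraries, which may be technical.

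The files listed 13880 genes. The recovered reads over them were 7661129 and 7606501 in tissue cells at steady state, 7625428 and 7015746 in vascular cells at steady state, 9297662 and 10343250 in infected tissue cells, and 9290215 and 9014402 in infected vascular cells. At these depths 3 reads corresponded to 0.29 to 0.428 CPM, for counting error only. T cell receptor complex genes were abundant in every group, with Cd3g between 8323 and 15221 and Cd3e between 4419 and 9651 in single libraries. Whether T cells in the sorts carried part of these reads was not tested.

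The infected vascular libraries stood apart. They listed 1459 and 1444 genes at 0, against 124 to 512 in the other 6 libraries, and their replicate correlation across genes was 0.849, against 0.947 to 0.975 in the other pairs. Their change from either reference group followed base composition: between infected and steady-state vascular cells the median log2 change was -1.32 among the genes of lowest GC content and 0.80 among those of highest GC content, with Spearman's rho 0.563 across 12672 genes, which are not independent replicates. The same rho was 0.515 between infected vascular and infected tissue cells, 0.125 for infection in tissue cells and -0.087 between compartments at steady state. Between the 2 libraries of a group rho was -0.208 in infected tissue and -0.156 in infected vascular cells. At steady state it was -0.081 in tissue and -0.094 in vascular cells, so replicates of every group differed somewhat along GC content. For transcript length rho was -0.336 for infection in tissue cells, -0.244 for infection in vascular cells, -0.186 between compartments after infection and -0.096 at steady state. The median log2 change of the shortest and the longest of 5 ranges of length was 0.206 and -0.406, 0.305 and -0.752, 0.12 and -0.558, and 0.093 and -0.062 in the same order. Removing each library's trend on GC content and transcript length was therefore added after the data had been seen, and is called the GC and length correction here. Of the called genes with an annotation, 90.4% kept call and direction at steady state, 63.6% for infection in tissue cells, 34.4% for infection in vascular cells and 40.1% between compartments after infection. In simulated data with 200 genes changed, 23 of 35 calls were false for infection in vascular cells, so its adjusted p-values may understate the error. Between compartments after infection 2 of 3 calls and in the interaction 6 of 8 were false, too few calls to give a rate.

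**Figure D1:**
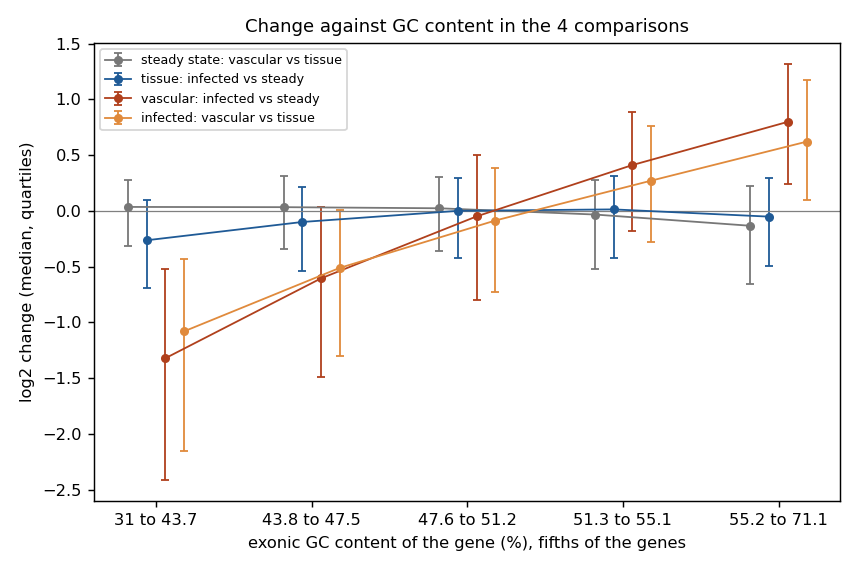
Median log2 change (y axis, bars give the quartiles) of the genes in each of 5 ranges of GC content in percent (x axis) for the 4 comparisons. GC content is that of a gene's longest transcript. In both comparisons with infected vascular cells the medians climb with GC content, to 0.62 and 0.80 in the highest range, while at steady state they stay between -0.134 and 0.035.

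Steady-state and infected libraries also differed in the marks of sex. Xist, the RNA that silences an X chromosome in female cells, was at 949 to 1680 in the 4 steady-state libraries and at 3.70 to 30.3 in the 4 infected ones. The summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 0 to 2.39 at steady state and at 768 to 2971 after infection. Infection and sex therefore cannot be told apart in any comparison of infected with steady-state cells, and the same holds for any other difference between these sets of mice.

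The first comparison asked how vascular differed from tissue ILC3s at steady state. Vascular cells carried a set of natural killer type receptor and effector genes: Ncr1, which encodes the activating receptor NKp46 (chromosome 7, 4337724 to 4345164, plus strand, mm10), was at 462 ± 27.4 against 15.2 ± 5.82, a 30.3-fold difference (log2 4.88, SE 0.31, adjusted p = 5.73e-08). The chemokine gene Ccl5 was at 3158 ± 222 against 149 ± 24.4, and the lectin-like receptor genes Klri2, Klrb1c and Klrc2 were 25.3-fold, 16.3-fold and 28.9-fold higher. The cytotoxic granule gene Gzma was 15.1-fold, the chemokine gene Ccl4 13.1-fold, the chemokine receptor gene Ccr10 16.7-fold and the lipid transfer gene Sec14l3 27.8-fold higher. The interferon lambda gene Ifnl3 had no read in tissue cells and was at least 40.7-fold higher in vascular cells, against a floor of 3 reads per library.

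A gene of circulation went the same way. S1pr1, the sphingosine phosphate receptor that guides lymphocytes out of tissue (chromosome 3, 115710433 to 115715072, minus strand), was 3.40-fold higher in vascular cells, at 5324 ± 104 against 1565 ± 86.3 (adjusted p = 9.21e-10). Il22 was at 516 ± 11.3 against 249 ± 37.8 and Il7r, the interleukin 7 receptor chain, at 24391 ± 1294 against 14189 ± 615, so both rose 2.07-fold and 1.72-fold. The residency markers Itgae and Cd69 were 1.71-fold and 1.18-fold higher in vascular cells and Gata3 1.18-fold higher, the calls of Cd69 and Gata3 hanging on single libraries. Csf2, Il17a, Il17f, Il23r, Ccr6, Tbx21 and Klf2 did not pass, with fitted folds between 1.02 and 1.33 in either direction.

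**Figure D2:**
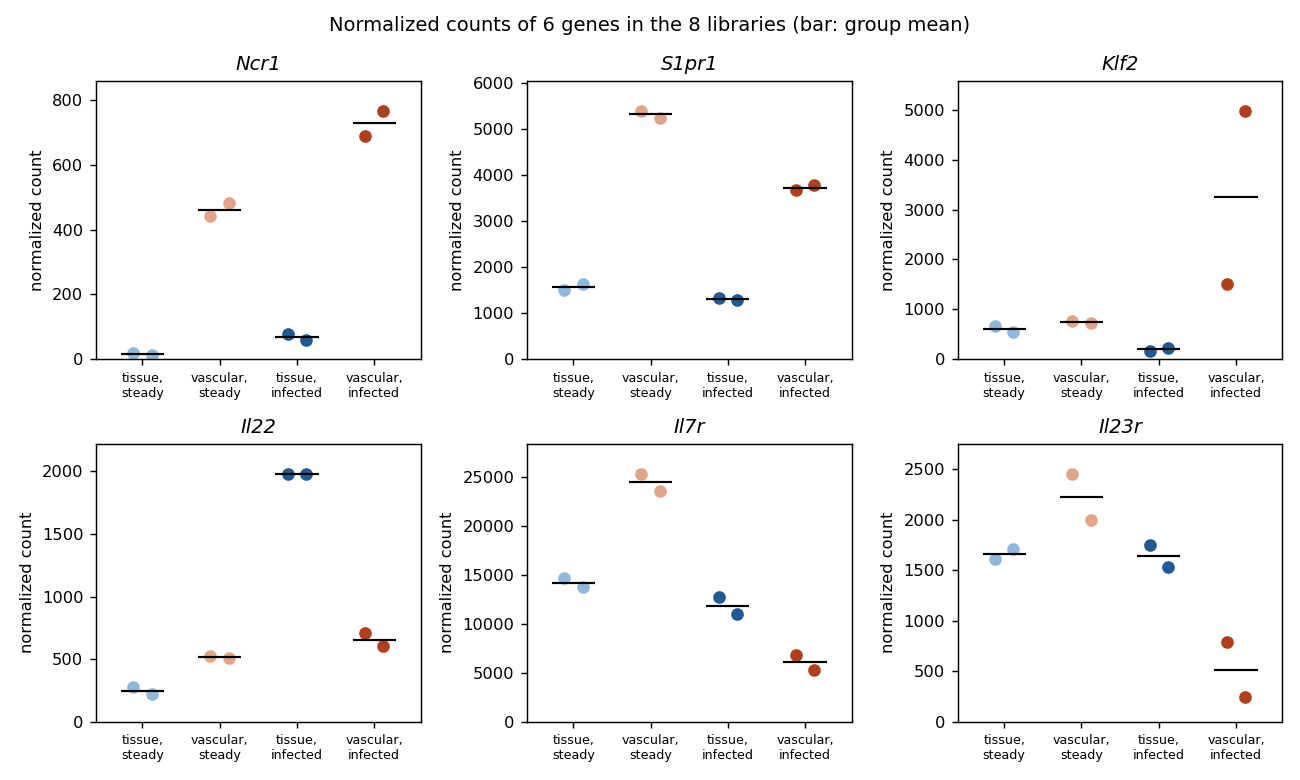
Normalized counts (y axis, linear from 0) of Ncr1, S1pr1, Klf2, Il22, Il7r and Il23r in the 8 libraries, a point per library and a bar at the mean of each group (x axis). Ncr1 and S1pr1 are higher in both vascular groups, and Il22 reaches 1982 in infected tissue cells against 249 at steady state.

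Tissue cells in turn carried matrix and mesenchymal genes. Mmp3, a matrix metalloproteinase (chromosome 9, 7445822 to 7455975, plus strand), was at 3334 ± 13.7 in tissue and 13.9 ± 0.725 in vascular cells, a 241-fold difference. Dclk1, Adamtsl3, Esm1 and Wisp2 had no read in vascular cells and were at least 44.0-fold, 43.9-fold, 36.0-fold and 24.8-fold lower there. Cd248 had 1 read in vascular against 450 in tissue cells, a ratio with a counting interval of 70.8 to 15684, and Angpt1 1 read against 265, with an interval of 41.5 to 9250.4. Podn, Ddr2 and Loxl1 were 71.6-fold, 46.2-fold and 33.2-fold lower in vascular cells.

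Of the lists fixed before the data were examined, that of natural killer cells and ILC1s moved most: 17 of 20 tested members rose in vascular cells and none fell (19 of 20 adjusted over the list alone; camera adjusted p = 1.98e-17, and 0.019 with an estimated correlation). Among them Gzmb had a log2 change of 3.41 and Klrk1 of 1.44. The list summed to 1075 and 1159 CPM in the tissue libraries against 3132 and 3222 in the vascular ones. Whether the ILC3s themselves or other cells in the vascular sort carried these reads was not tested. Egress and circulation genes rose in 12 of 19 cases, none falling (15 adjusted over the list alone; camera adjusted p = 4.89e-10), with Selplg at 0.70 and Tcf7 at 1.26. Interferon-stimulated genes rose in 12 of 33 cases and fell in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 6.73e-05), led by Irf7 at 2.16 and Ifit3 at 1.70. Regulatory and checkpoint receptors rose in 10 of 21 cases (11 adjusted over the list alone, with 1 lower), among them Tigit at 2.10 and Ctla4 at 1.00. All 4 of these lists stayed below 0.05 with an estimated correlation, at 0.019, 0.019, 0.039 and 0.039.

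Markers of other cell types moved too. Fibroblast and smooth muscle markers fell in 13 of 15 cases in vascular cells (13 adjusted over the list alone; camera adjusted p = 1.02e-12, and 0.019 with an estimated correlation), with Dcn at -3.58 and Mgp at -3.56. Their summed level was 3857 and 4001 CPM in the tissue libraries against 358 and 366 in the vascular ones. Neutrophil markers rose in 12 of 19 cases (12 adjusted over the list alone; adjusted p = 0.022 with an estimated correlation), with S100a8 at 2.24 and S100a9 at 2.25. They summed to 55 and 58 CPM in tissue against 201 and 210 in vascular libraries. Monocyte and macrophage markers rose in 8 of 21 cases and fell in 2, with Lyz2 at 1.73 and Fn1 at -4.17 (10 and 3 adjusted over the list alone; adjusted p = 0.066 with an estimated correlation). T cell markers rose in 7 of 17 cases and fell in 1, led by Cd28 at 0.93 (9 and 1 adjusted over the list alone; adjusted p = 0.10 with an estimated correlation), and ILC2 markers fell in 7 of 18 cases and rose in 1, with Il1rl1 at -2.36 (7 and 1 adjusted over the list alone; p 0.12).

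Class II antigen presentation genes rose in 7 of 16 cases, with Cd74 at 1.27 (7 adjusted over the list alone; adjusted p = 0.066 with an estimated correlation), NF-kB and TNF response genes in 9 of 26, with Nfkbia at 0.73 (9 adjusted over the list alone; p 0.12), and nuclear oxidative phosphorylation genes in 20 of 57, with Uqcrc1 at 0.44 (27 adjusted over the list alone; p 0.30), the GC and length correction leaving 10 of 56 called and the list call standing (camera adjusted p = 0.0012). No camera call was made for ILC3 identity, type 3 effector cytokines, lymphoid tissue inducer genes, tissue residency, chemokine receptors, STAT3 and IL-23/IL-1 response, immediate early and dissociation genes, glucocorticoid response, cell cycle, glycolysis and hypoxia, or the markers of B cells, dendritic cells, mast cells and basophils, endothelium, epithelium, and erythroid cells and platelets, with adjusted p from 0.054 to 0.96.

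Over all 13560 genes tested, 1268 were higher and 1318 lower in vascular cells. The edgeR quasi-likelihood test on the recovered reads called 397 and 388. With the GC and length correction, fitted on 12672 genes, 1376 and 1223 were called. On the same genes 1248 were higher and 1305 lower without the correction, of which 1132 and 1177 kept call and direction. The calls of Angpt1 and Ddr2 were lost with edgeR (adjusted p = 0.066 and 0.080). Lost too were that of Loxl1 without infected vascular replicate 7 or 8 (0.0873 and 0.0781), and those of Cd69 and Gata3 with edgeR (0.29 and 0.42). Cd69 was not called without any 1 of the 4 steady-state libraries (0.0583 to 0.191). Gata3 was not called in 5 of the fits without 1 library (0.0537 to 0.552), with a log2 change of 0.094 without replicate 4 of the vascular cells. Without replicate 4 of the vascular cells 620 genes were higher and 839 lower, and without replicate 3 of them 639 were higher.

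The second comparison followed infection in tissue cells. Il22, which encodes a cytokine acting on epithelium (chromosome 10, 118204942 to 118210047, plus strand), rose 7.95-fold, from 249 ± 37.8 to 1982 ± 1.72 (log2 2.99, SE 0.11, adjusted p = 6.25e-09). Interferon-induced genes rose with it, Ifit3 from 92.3 ± 12.5 to 1067 ± 3.41 and Ifit3b 12.5-fold. Saa3, an acute phase gene, had no read at steady state and was at least 168-fold higher, and the B cell chemokine gene Cxcl13, the membrane protein gene Ms4a4c and the globin gene Hbb-bs rose 9.42-fold, 8.49-fold and 9.13-fold. The other large rises were the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, at least 443-fold, 299-fold, 91.7-fold and 65.3-fold higher.

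Besides Xist, which fell 70.0-fold, the largest falls included the airway and alveolar epithelial genes Scgb1a1 (43.6-fold), Sftpa1 (19.3-fold) and Sftpc (19.0-fold), the matrix genes Hmcn1, Postn and Spp1 (6.66-fold, 6.07-fold and 5.17-fold), and the integrin gene Itga4 (5.59-fold). The nuclear RNAs Malat1 and Kcnq1ot1 fell 5.29-fold and 5.23-fold, Malat1 from 47783 ± 5758 to 9036 ± 1217. Of the genes followed throughout, Ncr1 rose 4.52-fold, to 68.9 ± 12.3, Csf2 2.31-fold, Itgae 1.98-fold, Cd69 by 0.58 on the log2 scale, Ccr6 1.39-fold and Gata3 1.21-fold. Klf2, a regulator of S1pr1, fell 3.07-fold, Tbx21 1.36-fold, S1pr1 1.19-fold and Il7r by a log2 change of -0.27. Il17a, Il17f and Il23r did not pass.

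As a group, interferon-stimulated genes rose in 20 of 33 cases and fell in 1, Gbp7 (23 and 1 adjusted over the list alone; camera adjusted p = 8.26e-15, and 0.021 with an estimated correlation). Ifit1 had a log2 change of 2.36 and Cxcl10 of 1.88. Nuclear oxidative phosphorylation genes rose in 54 of 57 cases, by a median of 0.44, with Cox4i1 at 0.62 (55 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). The GC and length correction left 36 of 56 called, the list median at 0.288 and the list call standing (camera adjusted p = 1.84e-11). Type 3 effector cytokines rose in 7 of 18 cases, among them Ltb at 0.60 and Lif at 1.16 (9 adjusted over the list alone; adjusted p = 0.070 with an estimated correlation). Cell cycle genes rose in 10 of 39, with Top2a at 0.74 (9; 0.070), glycolysis and hypoxia genes in 10 of 22, with Ldha at 0.52 (10 and 1 lower; 0.14), NF-kB and TNF response genes in 12 of 26, with Nfkbia at 0.98 (13 and 1 lower; 0.12), chemokine receptors in 8 of 17, with Ccr8 at 0.465 (8 and 3 lower; 0.11), natural killer and ILC1 markers in 10 of 20, with Gzmb at 1.07 (10 and 2 lower; 0.11), and checkpoint receptors in 6 of 21, with Cd274 at 0.78 (8 and 2 lower; 0.14), each bracket giving the count adjusted over the list alone and the adjusted p with an estimated correlation. Hk1, Rel, Ccr1, Tbx21 and Entpd1 were among the members of these lists that fell. The camera call of the checkpoint receptors ended with the GC and length correction (adjusted p = 0.126).

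Fibroblast and smooth muscle markers fell in 10 of 15 cases, with Fbln1 at -1.34 and Dcn at -0.60 (11 adjusted over the list alone; adjusted p = 0.070 with an estimated correlation). They summed to 2337 and 2328 CPM after infection against 3857 and 4001 before. Neutrophil markers rose in 10 of 19 cases, with Camp at 5.60 and S100a8 at 1.32 (11 adjusted over the list alone; adjusted p = 0.059 with an estimated correlation). Epithelial markers fell in 6 of 14 cases, with Sftpd at -4.24 (6 adjusted over the list alone; camera adjusted p = 0.123, and 0.0092 with the GC and length correction). They summed to 30 and 32 CPM against 227 and 218. The other lists were not called by camera, with adjusted p from 0.054 to 0.897.

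In all, 1755 genes were higher and 1894 lower after infection, a share of 48.1% higher. DESeq2 called 678 and 496 (57.8% higher) and edgeR's quasi-likelihood test on the recovered reads 339 and 187 (64.4% higher). With the GC and length correction, fitted on 12672 genes, 1878 and 1015 were called (64.9% higher). On the same genes 1702 were higher and 1738 lower without the correction, of which 1261 and 926 kept call and direction. The calls of Il7r and Csf2 ended with the correction (adjusted p = 0.19 and 0.081). The calls of Ifit3b, Cxcl13, Hmcn1, Postn, Klf2, Tbx21, Ccr6, Gata3 and S1pr1 were not made by edgeR (adjusted p from 0.065 to 0.30), and sex was confounded with infection throughout. The call of Csf2 was lost without any 1 of the 4 tissue libraries (adjusted p from 0.0819 to 0.182) and that of Il7r without either of 2 of them (0.0757 and 0.0918). Those of Gata3, S1pr1, Tbx21 and Cxcl13 were each lost without 1 library (0.0501 to 0.0648). Without replicate 5 of the infected tissue cells 1082 genes were higher and 1120 lower, without replicate 6 of them 1221 were lower, and without replicates 1 or 2 of the steady-state tissue cells 1031 or 1164 were lower.

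**Figure D3:**
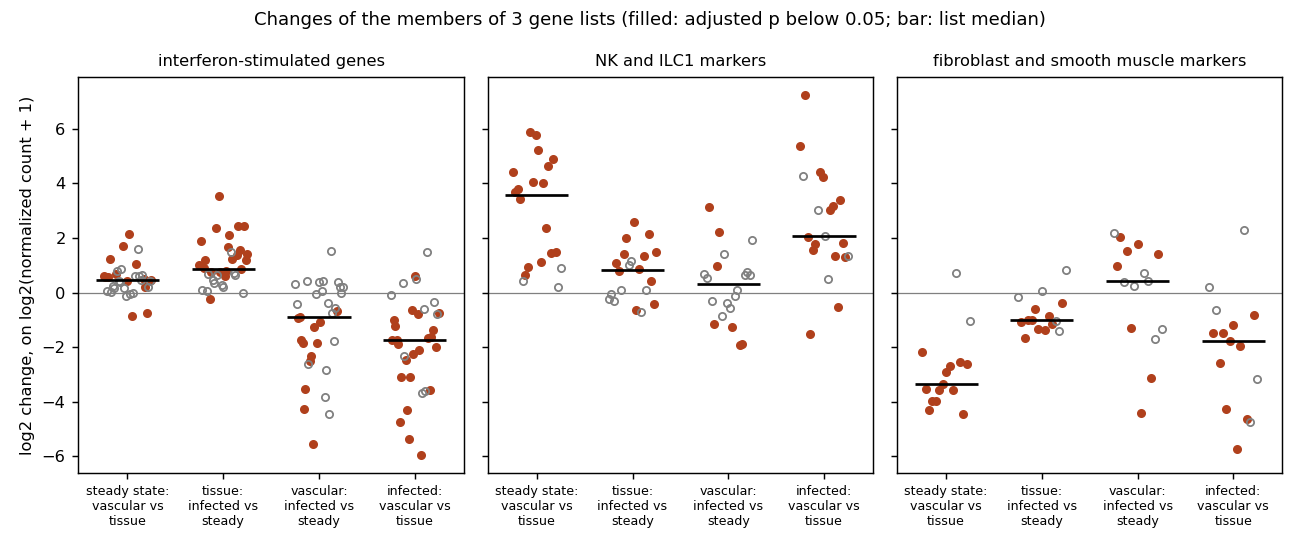
Log2 change (y axis) of each tested member of 3 gene lists in the 4 comparisons (x axis), with filled points for adjusted p below 0.05 and a bar at the list median. The median of the interferon-stimulated genes is 0.863 for infection in tissue cells and -0.907 for infection in vascular cells.

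The third comparison followed infection in vascular cells. The largest rises were of genes of several kinds. Mcpt8, a basophil protease (chromosome 14, 56082166 to 56085273, minus strand), had no read at steady state and was at least 108-fold higher, at 374 ± 82.7, and Fcer1a, the IgE receptor chain, was at least 37.0-fold higher. Cyp11a1, which makes pregnenolone from cholesterol (chromosome 9, 58006411 to 58027023, plus strand), went from 1 read in both libraries together to 919, a ratio with a counting interval of 131 to 28879. The neutrophil granule gene Ngp had 1 read against 703, with an interval of 99.95 to 22099, and the acute phase gene Saa3 was at least 64.9-fold higher. Pgf had 2 reads against 628, with an interval of 68.8 to 2065, Wisp2 and Alox15 were at least 40.5-fold and 43.1-fold higher, and the Y-linked gene Eif2s3y at least 60.9-fold.

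The largest falls were Kcnq1ot1, a long RNA of an imprinted locus (chromosome 7, 143203458 to 143296549, minus strand), from 631 ± 63.2 to 0.454 ± 0.642 with 1 read left, and Casp8ap2, Haus3, Alkbh8, Pibf1, Trim23, Zfp280c and Cntln, of which Casp8ap2 fell 120-fold, Haus3 130-fold, Alkbh8 170-fold and Pibf1 135-fold. Trim23 had 3 reads against 499, with a counting interval of 71.2 to 1018 for the ratio, Zfp280c 1 read against 265, with an interval of 59.3 to 13219, and Cntln fell at least 42.9-fold. Sec14l3 and Ifnl3, both high in vascular cells at steady state, had no read after infection and were at least 118-fold and 45.1-fold lower. Il7r fell 4.04-fold, from 24391 ± 1294 to 6044 ± 1143 (adjusted p = 5.8e-07), and Il23r 4.32-fold. S1pr1 fell 1.43-fold and Cd69 1.51-fold. Klf2 rose 4.41-fold with libraries far apart (3250 ± 2455), Itgae 1.70-fold and Ccr6 1.65-fold. Without replicate 8 of the infected vascular cells the log2 change of Klf2 was 1.04. Il22 was at 656 ± 71.6 against 516 ± 11.3 and did not pass (adjusted p = 0.39), nor did Ncr1, Tbx21, Gata3, Il17a, Il17f or Csf2.

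By list, mast cell and basophil markers rose in 6 of 9 cases (7 adjusted over the list alone; camera adjusted p = 3.41e-06, and 0.089 with an estimated correlation), with Hdc at 3.51 and Gata2 at 2.73. They summed to 371 and 372 CPM against 29 and 28. Neutrophil markers rose in 7 of 19 cases, with S100a8 at 2.16 (7 adjusted over the list alone; p 0.089), and ILC2 markers in 6 of 18, with Il17rb at 1.58 and Hs3st1 at 1.24 (7 alone; p 0.17). Immediate early and dissociation genes rose in 16 of 25 cases and fell in 2, with Egr1 at 1.97, Zfp36 at 1.75 and Hsp90aa1 at -2.17 (16 and 2; 0.23). Type 3 effector cytokines rose in 5 of 18 cases, with Ccl4 at 5.53 and Ccl3 at 6.32 (6 and 1 lower; 0.17), glycolysis and hypoxia genes in 9 of 22, with Aldoa at 1.08 (12 and 1 lower; 0.30), oxidative phosphorylation genes in 24 of 57, with Cox4i1 at 1.05 (28 and 1 lower; 0.34), and NF-kB and TNF response genes in 10 of 26, with Icam1 at 1.13 (13 and 2 lower; 0.25), the brackets giving the count adjusted over the list alone and the adjusted p with an estimated correlation. Over all genes Tnfsf11, Ero1l, Map3k8 and Rel of these lists fell. Ccl3 and Ccl4 also belong to the NF-kB and TNF response list, and Il22, Il17a, Il17f and Csf2 of the type 3 list did not pass. The GC and length correction left 8 of the 25 immediate early genes, 4 of 21 glycolysis genes, 16 of 56 oxidative phosphorylation genes and 4 of 18 ILC2 markers called higher. The list medians went from 0.932 to 0.391, 0.575 to 0.253, 0.486 to 0.287 and 1.161 to 1.228, and camera still called all 4 lists (adjusted p = 0.044, 0.047, 0.00072 and 0.0014). Glucocorticoid response genes rose in 5 of 15 cases, with Txnip at 1.03, and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), and that camera call ended with the GC and length correction (adjusted p = 0.17).

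Interferon-stimulated genes fell in 13 of 33 cases and none rose, with Ifit2 at -5.55, Gbp7 at -3.52 and Ifit1 at -2.33 (15 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.0137, and 0.17 with an estimated correlation). With the GC and length correction 6 members were called lower and 1 higher, the list median was -0.636 and camera called the list lower still (adjusted p = 0.00072). The other lists were not called by camera, with adjusted p from 0.0913 to 0.983. Of these, camera with the GC and length correction called epithelial markers lower (adjusted p = 0.034) and natural killer and ILC1 markers higher (adjusted p = 0.0497).

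In total 1257 genes were higher and 2222 lower in infected than in steady-state vascular cells, against 2303 and 3120 with edgeR. With the GC and length correction 863 and 867 were called. With it the calls of Klf2, Itgae and Ccr6 ended (adjusted p = 0.20, 0.12 and 0.12), Cd69 turned from a fall to a rise (log2 1.40), Il22 passed as higher (adjusted p = 0.0059), and Il7r remained lower (log2 -0.77). Without replicate 8 of the infected vascular cells the counts were 474 and 1619 and the calls of Alox15, Ifnl3, Klf2, Itgae, Ccr6 and S1pr1 were lost (adjusted p from 0.0999 to 0.252). Without replicate 7 they were 659 and 1821 and those of Ngp, Ifnl3, Ccr6 and S1pr1 were lost (0.0567 to 0.135). The calls of Itgae and Ccr6 were lost also without replicate 4 of the steady-state vascular cells, and that of S1pr1 without replicate 3 of them. Sex was confounded with infection here too.

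The fourth comparison set vascular beside tissue cells after infection. The chemokine genes Ccl4 and Ccl3 were 239-fold and 230-fold higher in vascular cells, Ccl4 at 6504 ± 333 against 27.2 ± 7.04 (chromosome 11, 83662584 to 83664683, plus strand; adjusted p = 2.83e-05), and Gzma and Ccl5 were 169-fold and 41.0-fold higher. Cyp11a1 had no read in tissue cells and was at least 167-fold higher, while Mcpt8, Fcer1a and Cd200r3, all found on basophils, had 2, 2 and 1 reads in tissue cells against 816, 280 and 323, with counting intervals of 123 to 3684, 41.9 to 1268 and 62.8 to 13970.5 for the ratios. Ccl9 was 99.0-fold and the phosphodiesterase gene Pde2a 53.0-fold higher. Of the exonic bases of Pde2a 64.3% are shared with another gene, so its reads are uncertain. Of the followed genes, Ncr1 was 10.6-fold, S1pr1 2.84-fold and Tbx21 2.48-fold higher in vascular cells. Klf2 was 16.6-fold higher with its 2 libraries far apart, its log2 change of 3.82 being 2.96 without replicate 8 of the infected vascular cells and 4.68 without replicate 7.

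Lower in vascular cells were mesenchymal genes, with 1 or 2 reads left of Ogn, Gpc6, Srpx and Aspn, whose ratios had counting intervals of 162 to 4861, 103 to 22829, 80.8 to 17908 and 65.5 to 1968. Abcc9, Gpm6b, Snx7 and Meox2 had no read and were at least 50.5-fold, 38.1-fold, 37.5-fold and 37.4-fold lower, Sfrp4 was 113-fold lower, and Trim23 had 3 reads against 492 (51.1 to 731). Il22 was 3.02-fold lower in vascular than in tissue cells, at 656 ± 71.6 against 1982 ± 1.72 (adjusted p = 0.00063). Il23r, Il7r and Cd69 were 3.18-fold, 1.96-fold and 1.92-fold lower. Il17a, Il17f, Csf2, Ccr6, Gata3 and Itgae did not pass.

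Interferon-stimulated genes were lower in vascular cells in 22 of 33 cases and higher in 1, Irf1 (22 and 3 adjusted over the list alone; camera adjusted p = 3.62e-07, and 0.024 with an estimated correlation), with Gbp7 at -3.09 and Ifit1 at -4.29. Of these 22, 18 remained called lower with the GC and length correction. Natural killer and ILC1 markers were higher in 13 of 20 cases and lower in 2, Ifng and Klrk1 (14 and 2 adjusted over the list alone; adjusted p = 0.024 with an estimated correlation). Egress and circulation genes were higher in 14 of 19 cases and lower in 1, Ccr2 (14 and 1 adjusted over the list alone; adjusted p = 0.024 with an estimated correlation). Mast cell and basophil markers were higher in 5 of 9 cases, with Cpa3 at 4.31 (7 adjusted over the list alone). Neutrophil markers were higher in 7 of 19, with Il1b at 2.44 (9 adjusted over the list alone). Both lists had adjusted p = 0.024 with an estimated correlation. Neutrophil markers summed to 858 and 799 CPM in vascular against 107 and 102 in tissue libraries.

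Fibroblast and smooth muscle markers were lower in 10 of 15 cases, with Lum at -5.72 and Col1a2 at -2.57 (11 and 1 higher adjusted over the list alone; adjusted p = 0.052 with an estimated correlation). Immediate early and dissociation genes were higher in 15 of 25 cases, with Ier2 at 1.32 (16 and 2 lower; 0.11), class II genes in 6 of 16, with Cd74 at 1.21 (7 and 1 lower; 0.075), NF-kB and TNF response genes in 9 of 26, with Il1b at 2.44 (10 and 2 lower; 0.12), monocyte and macrophage markers in 6 of 21, with Lyz2 at 1.45 (7 and 1 lower; 0.11), endothelial markers in 8 of 21, with Cldn5 at 1.94 (10 and 3 lower; 0.23), and oxidative phosphorylation genes in 8 of 57, with Cox5b at 0.58 (3; 0.39), the brackets giving the count adjusted over the list alone and the adjusted p with an estimated correlation. Over all genes Hsp90aa1, Ctss, Map3k8, Apoe, Calcrl and Cycs were among the members lower in vascular cells. Called higher with the GC and length correction were 2 of the 16 class II genes, 3 of the 21 endothelial markers and 11 of the 25 immediate early genes. Their list medians went from 1.027 to 0.776, 0.473 to 0.34 and 0.905 to 0.507, and camera still called these lists (adjusted p = 0.0034, 0.0081 and 8.59e-05). Glycolysis genes, higher in 7 of 22 cases and lower in 2 (10 and 2 adjusted over the list alone), and glucocorticoid response genes, higher in 4 of 15 and lower in 1 (5 and 1), were called by camera but not with the GC and length correction (adjusted p = 0.23 and 0.16) and not with an estimated correlation (adjusted p = 0.24 and 0.14). The other lists were not called, with adjusted p from 0.0633 to 0.824. Of these, camera called T cell markers higher with the GC and length correction (adjusted p = 0.0034), with 8 of 17 members higher and 2 lower.

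**Figure D4:**
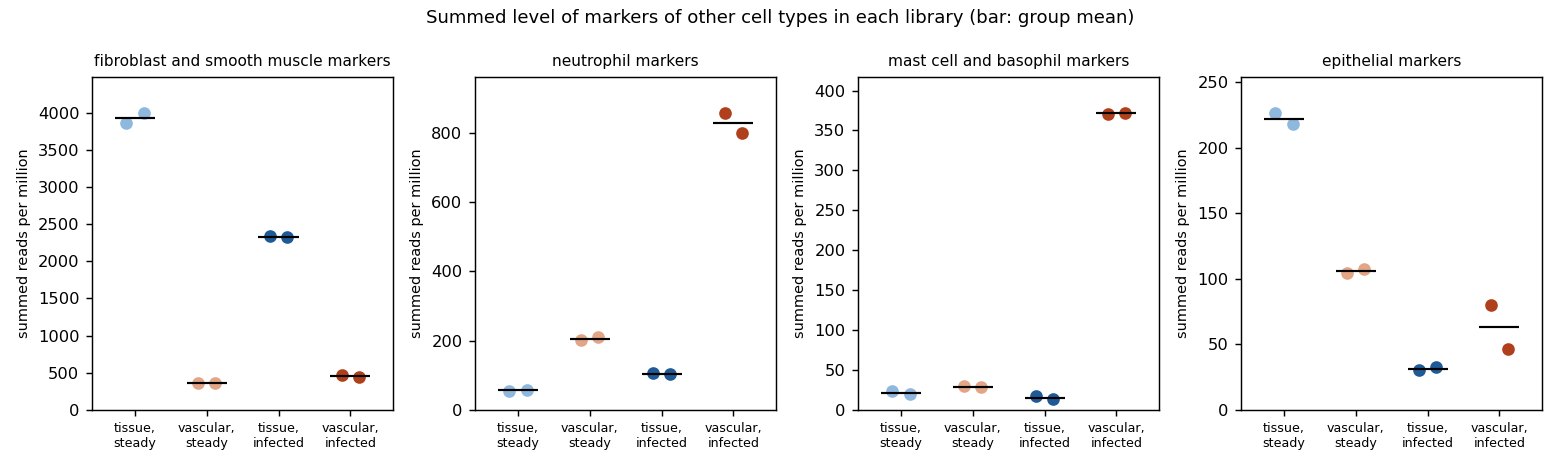
Summed CPM (y axis, linear from 0) of the markers of 4 other cell types, a point per library and a bar at the mean of each group (x axis). Fibroblast and smooth muscle markers are highest in tissue cells at steady state (3857 and 4001) and mast cell and basophil markers in infected vascular cells (371 and 372).

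Over all genes, 896 were higher and 1995 lower in infected vascular than in infected tissue cells, against 1636 and 2842 with edgeR and 695 and 880 with the GC and length correction. The correction ended the call of Tbx21 (adjusted p = 0.18), left Il7r at a log2 change of 0.07 (0.68) and turned Cd69 from lower to higher (log2 0.68). Without replicate 8 of the infected vascular cells 276 and 1327 genes were called, and without replicate 7 the counts were 474 and 1535.

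The interaction asked whether infection changed the compartments differently. Sex was confounded with infection in both compartments, so an effect of sex that differs between compartments cannot be told apart from it. The change of Il22 was larger in tissue than in vascular cells (a log2 difference of -2.65, adjusted p = 4.29e-05). In vascular cells its change did not pass in the reported fit but passed as higher with the GC and length correction. With that correction the difference was smaller. Il7r fell more in vascular cells (-1.76). Il23r, at a log2 change of -0.02 in tissue cells, fell in vascular cells (a difference of -2.31). Klf2 and Tbx21 moved up relative to tissue cells (3.52 and 1.09), Klf2 by 2.66 without replicate 8 of the infected vascular cells. Cyp11a1, Mcpt8, Cd200r3 and Slc45a3 led the genes that rose more in vascular cells, with Cd248, and Sec14l3, Trim23, Ifnl3, Krt79 and Bmt2 those that fell more. By camera p the interferon-stimulated genes came first among the lists, with 25 of 33 lower in the vascular response and none higher, at a median of -2.12 (27 adjusted over the list alone; adjusted p = 0.038 with an estimated correlation). Mast cell and basophil markers had the larger median, 4.03, with 6 of 9 higher (adjusted p = 0.061 with an estimated correlation). In all 771 genes were higher and 1664 lower, against 422 and 669 with the GC and length correction. Of the called genes with an annotation, 32.7% kept call and direction with it. The correction ended the difference of Tbx21 (adjusted p = 0.84) and turned that of Cd69 (log2 -1.18) to 0.43. Without replicate 8 of the infected vascular cells 227 genes were higher. The lists not called had adjusted p from 0.124 to 0.978.

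Infection raised 525 genes and lowered 826 in both compartments, where independent lists would share 163 and 310. These counts depend on the tool: edgeR with TMM factors gave 232 and 140, limma without weights 217 and 102, and the GC and length correction 510 and 206, and without replicate 7 of the infected vascular cells 266 were raised in both. Across genes the log2 changes of the compartments had a Pearson correlation of 0.307 and a Spearman's rho of 0.306, genes not being independent replicates. Higher in vascular cells under both conditions were 342 genes and lower 316, where 83.8 and 194 would be shared by independent lists. Across genes the Pearson correlation was 0.309 and Spearman's rho 0.174. Between the compartments 168 genes were higher at steady state and lower after infection, and 61 the reverse. For infection 123 genes rose in tissue and fell in vascular cells, and 111 the reverse. No count under independent lists was computed for these opposite directions, so they are not shown to exceed it. With edgeR and TMM factors 199 were higher and 211 lower under both conditions. No library entered both sides of either overlap, but sex differed between the conditions in both compartments alike.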

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

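The tests of the few molecules behind the reads and of sex, and the GC and length correction itself, were chosen after the results had been seen. The edgeR test on recovered reads was the test of the fixed design. The results here differ between compartments by the interaction of infection with compartment, a test of the difference itself, given as log2 differences of vascular minus tissue cells. Sex was confounded with infection in this test too.

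Genes that rose more in vascular cells were Cyp11a1 (8.17), Mcpt8 (7.8), Slc45a3 (7.63), Cd200r3 (7.61) and Cd248 (7.56). Genes that fell more were Sec14l3 (-7.73), Trim23 (-7.06), Ifnl3 (-6.96), Krt79 (-6.63) and Bmt2 (-6.47). With edgeR on recovered reads Cyp11a1, Mcpt8 and Ifnl3 had an adjusted p of 1. Without replicate 8 of the infected vascular cells the adjusted p of Slc45a3, Krt79 and Ifnl3 was 0.0782, 0.05 and 0.206, and without replicate 7 that of Ifnl3 was 0.174. That of Cd200r3 was 0.0569 without replicate 3 of the steady-state vascular cells and 0.0524 without replicate 5 of the infected tissue cells.

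Of the genes followed throughout, Il22 differed by -2.65, Il23r by -2.31, Il7r by -1.76, Cd69 by -1.18, Tbx21 by 1.09 and Klf2 by 3.52. With the GC and length correction these were -1.71, -1.40, -0.70, 0.43, 0.12 and 2.45, so that Cd69 turned and the call of Tbx21 ended (adjusted p = 0.84). The adjusted p of Tbx21 was 0.0817 without replicate 7 of the infected vascular cells.

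Among the lists the interferon-stimulated genes had a camera adjusted p of 1.15e-10, mast cell and basophil markers 3.03e-07, immediate early and dissociation genes 0.00252, fibroblast and smooth muscle markers 0.00325, ILC2 markers 0.00402, endothelial markers 0.0199, and glucocorticoid response genes and neutrophil markers 0.0476 each. With an estimated correlation the first had an adjusted p of 0.038 and the others, in the same order, 0.061, 0.38, 0.19, 0.21, 0.38, 0.26 and 0.26. With the GC and length correction the immediate early and glucocorticoid lists were not called (adjusted p = 0.35 and 0.20).

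Many genes changed in the infected vascular libraries, and much of this may be technical. Only 34.4% of the genes called against steady-state vascular cells kept their call and direction once each library's trend on GC content and length was removed, so this trend is a candidate source of a large part of the calls. The share of genes at 0 reads in exactly 1 of the 2 libraries was 10.97%, against 1.02 to 3.94% in the other pairs, which would follow if few molecules lay behind the reads. The trend is argued against as the whole source of the lower interferon-stimulated genes, of which 18 of 22 stayed called lower against infected tissue cells, with a median log2 change of -1.94 before and -1.57 after. Against steady-state vascular cells the whole list went from 13 to 6 members called lower, with 1 higher, and its median from -0.907 to -0.636, so there the trend stays open as a source of many of the calls of single members. The list itself stayed called lower there, with a camera adjusted p of 0.0137 before and 0.00072 after. A difference of the vascular cells in their response to infection stays open for these genes.

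Infection and steady state differ also by the sex of the mice: in 8 of 8 libraries the levels of Xist and of the Y-linked genes followed the condition. Sex and infection therefore cannot be told apart, since no library of either condition carried the marks of the other sex. Of the tested X-linked genes 28.8% were called for infection in tissue cells, against 26.8% of autosomal genes, and 31.3% against 25.9% in vascular cells, so most calls lay on autosomes, which sex can change too.

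Genes of other cell types differ between the sorts, which were made on the eGFP reporter. How fully the sorts left out fibroblasts and basophils was not measured. On a second fibroblast list, 22 of 22 genes (100%) were called lower in vascular cells at steady state, with Gsn at 3227 against 44091, Timp3 at 1328 against 9254 and Serping1 at 737 against 8436, so fibroblasts or their free RNA in the tissue sort may account for the matrix genes there. After infection 13 of 22 (59.1%) were lower and 1, Ltbp4, higher in vascular than in tissue cells. With infection 10 of 22 rose and 1, Serpinf1, fell in vascular cells (median log2 change 1.33). In tissue cells 15 of 22 fell and none rose (median -0.93), so the difference between the sorts was smaller then. No value of this list was taken with the GC and length correction. For basophils or their free RNA in the infected vascular sort the second list did not decide, with 36.4% (4 of 11) called higher than in infected tissue cells: Csf1, Ifitm1, Fcer1g and Lilrb4a. Fcer1g and Lilrb4a were called higher in vascular cells at steady state already (log2 2.43 and 1.89), and with infection in vascular cells Fcer1g rose further (log2 1.32, adjusted p = 0.0025) while Lilrb4a did not pass (0.42, adjusted p = 0.56). Expression of such genes by ILC3s themselves stays open and was not tested. How many genes of the second lists ILC3s express was not determined. No second list was tested for natural killer cells, T cells, neutrophils or monocytes, so such cells or their free RNA in either sort stay open.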

How the results depend on the processing

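Chosen after the data had been seen were limma without weights, pseudocounts of 0.5 and 8, TMM scaling and leaving out both infected vascular libraries. So were the block and the GC and length correction. The edgeR test with TMM factors on recovered reads was the test of the fixed design. Of the alternative values of counts of genes 237 stayed within 1.5 times the reported count and 63 did not. Of the values of named genes 3381 kept direction and side of the threshold, 55 gained a call, 118 lost it and 4 reversed, and of those of lists 1421 kept them, 50 gained and 69 lost a call. The estimated correlation ended 42 of the list calls, and fry gained 29 and lost 1. The GC and length correction gained 7 and lost 6. Gained was, among others, that of immediate early and dissociation genes at steady state (camera adjusted p = 0.015). Leaving out 1 library also lost some list calls. No filter, the stricter filter, both pseudocounts, TMM scaling and fits on only the 2 groups compared left every count within 1.5 times. Without both infected vascular libraries 1290 genes were higher and 1394 lower at steady state, and 1728 and 2212 after infection in tissue cells. The labels give no pairing, because they number the libraries without repeating a number, and the meaning of the number ending the column name is not stated. A block on that number moved no count by over 1.5 times and added a call of Tbx21 for infection in vascular cells. Unless said, the cause of a difference was not tested. Depth limits genes near 3 reads.

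For vascular against tissue cells at steady state, genes higher numbered 686 with DESeq2, 436 with edgeR and median ratio factors, 450 without weights and 397 with edgeR and TMM factors, and genes lower 642, 375, 454 and 388. For the same after infection, genes higher numbered 2126, 1844, 1865 and 1636 with these tools and 1500 with voom, and genes lower 880 with the GC and length correction. For infection in vascular cells, genes higher numbered 2643, 2389, 2436 and 2303, and genes lower 867 with the correction. For infection in tissue cells, genes higher numbered 678, 341, 304 and 339, and genes lower 496, 190, 143 and 187, and 1015 with the correction. For the interaction, genes higher numbered 1256 with DESeq2 and 422 with the correction, and genes lower 669 with the correction. Raised by infection in both compartments were 239 genes with edgeR and median ratio factors, 217 without weights and 232 with edgeR and TMM factors, and lowered in both 142, 102 and 140, with 343 for DESeq2 and 206 with the correction. Higher in vascular cells under both conditions were 199 with edgeR and TMM factors, and lower 198 with edgeR and median ratio factors.

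Fits without 1 library kept each remaining library at its group's weight from the fit of all 8 libraries. The spread of a group left with 1 library was assumed from that weight, not measured. The weight drew on the library left out too, so these counts are not independent of it. Leaving out 1 library at a time gave 620 to 1322 genes higher and 839 to 1395 lower at steady state. It gave 276 to 962 higher and 1327 to 1898 lower between compartments after infection, and 474 to 1208 higher for infection in vascular cells. It gave 1082 to 1781 higher and 1031 to 2155 lower for infection in tissue cells, and 227 to 835 higher in the interaction. Shared by both compartments it left 266 to 445 genes raised and 486 to 808 lowered by infection, and 192 to 331 higher in vascular cells under both conditions.

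With the GC and length correction Il7r turned to a log2 change of 0.074 between compartments after infection, and Cd69 to 0.68 there, to 1.40 for infection in vascular cells and to 0.43 in the interaction. By construction the correction removes changes that follow GC content and length.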

Other observations

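These values were chosen after the data had been seen and are given without explanation. Ribosomal protein genes took 3.32 and 3.35% of the reads in steady-state tissue libraries, 3.75 and 3.87% in steady-state vascular ones, 4.41 and 4.45% in infected tissue ones and 6.67 and 6.67% in infected vascular ones. Malat1, a nuclear RNA, took 0.664 and 0.568%, 0.501 and 0.442%, 0.119 and 0.0998%, and 0.0586 and 0.0385% of the reads in the same order. T cell markers summed to 5350 and 5332 CPM in steady-state tissue, 6165 and 6146 in steady-state vascular, 6012 and 5707 in infected tissue and 6545 and 6353 in infected vascular libraries. The labels used here name the eGFP reporter as the basis of the sort.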
